A study of Danio rerio with 12 samples.

How the data were processed

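RNA from whole zebrafish embryos was sequenced in 12 libraries, with 3 libraries in each of 4 groups: wild-type controls and embryos mutant for snapc3, lsm8 or tnpo3. Per the labels' protocols, total RNA was isolated with TRI Reagent, treated with DNase, and made into stranded libraries after removal of ribosomal RNA with a Ribo-Zero kit. Developmental stage is not given in the sources used here, nor is whether a library came from a single embryo or a pool. Every limma p-value therefore measures only the spread between these libraries. Fisher's exact tests, binomial tests and length tests count genes, exons or introns. These units are not independent replicates, and such p-values do not measure the spread between libraries. Per the labels, the control libraries carry strain backgrounds A, B and C, 1 library each, whereas the snapc3 mutant libraries all carry background A, the lsm8 mutant libraries B and the tnpo3 mutant libraries C. Background did not enter any model as a covariate, because the counts in the splicing tables are not matched to replicate numbers and the deposited expression tables have no values per library.

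Per the submitters' processing notes, the authors used TopHat2 2.0.13, Bowtie2 2.2.3, featureCounts 1.4.5-p1 and limma 3.26.3 with genome build Zv9. Their settings are not given in the sources used here. For each mutant the authors deposited a table of log2 fold change against wild type with average log2 expression, a moderated statistic, a log-odds score, a p-value and an adjusted p-value per gene. Each of these tables lists only genes with an adjusted p below 0.05 and an absolute log2 fold change of at least 1. The ratio of p-value to adjusted p-value in the deposited tables points to 33737 genes tested, since that number turned 38.8%, 42.9% and 24.3% of the ratios in the snapc3, lsm8 and tnpo3 tables into whole ranks within 1e-06. Genes absent from a deposited table are not counted as unchanged. The standard error printed beside a fold change is the deposited log2 fold change divided by the deposited moderated statistic. The deposited score of log-odds was not used. Gene symbols come from the deposited tables, and the gene name reference matched 357, 629 and 93 of the listed identifiers in the snapc3, lsm8 and tnpo3 tables.

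For each mutant the authors also deposited a table of retained introns and a table of skipped exons, with junction read counts for inclusion and skipping in 3 control and 3 mutant libraries, the lengths of both forms, and a deposited p-value and FDR per event. The columns have the layout of rMATS junction counts. The tool and its version are not given in the sources used here. The control counts were identical in the tables for every event they shared, which fixed the control columns. The order of libraries within a cell is not matched to replicate numbers. Inclusion is the share of reads with the exon or intron, after division of each count by its form length, and differences are mutant minus control.

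The splicing tables were tested with limma 3.58.1 in R 4.3.3 (trend and robust options) on the log2 ratio of length-normalised inclusion to skipping counts with a pseudocount of 0.5. Tested events had a mean of at least 10 reads per library and at least 1 read of each form. An event was called at a Benjamini-Hochberg adjusted p below 0.05 and a difference of group mean inclusion of at least 10 percentage points. Each mutant was compared with the controls alone, and pairs of mutants were compared by a contrast of mutant minus mutant with the controls in the fit. Other tests ran in SciPy 1.17.1. These were Fisher's exact test for gene lists and for the overlap of expression with splicing, the exact binomial test for direction, and permutation tests with 100000 resamples for lengths, all two-sided. Direction of a list was tested only where at least 5 members were in a deposited table, which gave 11 tests. Intervals of shares are exact Clopper-Pearson intervals at 95% and cover counting error only.

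The design, the thresholds, 28 gene lists, the naming rule and most alternatives were chosen before the data were examined. Named genes are the mutated genes, the 10 highest and 10 lowest log2 fold changes with a gene symbol, and up to 4 members per list with the smallest adjusted p, with every listed member of the T lymphocyte list. Named splicing events are the 6 with the largest difference per event type with a mean of at least 20 reads, and every call in genes of the lists for T lymphocytes, SR proteins, the core spliceosome, LSm proteins and snRNA transcription and of 1 further list. The alternatives were the deposited FDR with the same minimum difference, a quasi-binomial model, read minimums of 20 and none, a pseudocount of 2, no minimum difference or one of 20 points, a fit over all groups, each library left out in turn, and an adjusted p threshold of 0.01 for expression. Added after the data were seen were a limma fit of junction reads of the skipped-exon tables summed per gene (mean of at least 20 reads), 4 restrictions of the direction test, exon lengths, gene lists among genes with called exons, and the tests of explanations in the closing part.

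The scripts were tested on simulated counts before use. Of simulated changes of 3 log2 units in retained introns, 53.7% were called in the snapc3 setting, 71.6% in lsm8 and 62.7% in tnpo3, out of 67 introns each. In skipped exons the shares were 27.3% of 66, 32.3% of 65 and 38.8% of 67 exons, so many real changes of that size can be missed. The quasi-binomial model called 0% of the simulated exon changes of that size. Simulated changes went in both directions and were placed only in events away from full and from no inclusion. Tested exons had a median control inclusion of 99.8%, 99.9% and 100% in the snapc3, lsm8 and tnpo3 tables. The shares thus do not speak for exons at full inclusion.

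Over the tables, which hold different events, libraries held 12772103 to 22999590 junction reads in the skipped-exon tables and 332977 to 542810 in the retained-intron tables. Libraries of a group differed by more than sampling noise, with a chi-square of 6.82 to 28.9 per event between pairs. Total library sizes cannot be read from these files.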

Results

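RNA sequencing of whole zebrafish embryos compared mutants of 3 genes of RNA processing, found in screens for T cell development, with wild-type controls, to ask which transcripts and splicing events change. The gene snapc3 encodes a subunit of the complex that drives transcription of small nuclear RNA (snRNA) genes. The lsm8 product belongs to the ring of LSm proteins that binds U6 snRNA in the spliceosome. The tnpo3 product is an import receptor that carries SR splicing proteins into the nucleus. Each group has 3 libraries. Each table holds its own set of events, so the same control libraries have other totals in each. In the skipped-exon tables, junction reads per library were 12772103 to 14288586 in controls and 13039814 to 15025631 in mutants for snapc3, 20118005 to 22999590 and 14668691 to 18478988 for lsm8, and 16340782 to 18650509 and 15711487 to 18300285 for tnpo3. In the retained-intron tables they were 464358 to 533644 and 469886 to 542810, 462622 to 532082 and 332977 to 425613, and 464001 to 533354 and 440976 to 534644. Every lsm8 mutant library thus held fewer junction reads than every control library in both lsm8 tables. These sums depend on the events in a table and do not give total library sizes. Each mutant group carries a single strain background, which it shares with only 1 control library, and no model below separates mutation from background.

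The mutated genes were examined first. In the authors' deposited table for snapc3 mutants, snapc3 had a log2 fold change of −1.39 (SE 0.19, limma adjusted p = 0.0298). In the authors' deposited table for tnpo3 mutants, tnpo3 had a log2 fold change of −1.51 (SE 0.06, limma adjusted p = 0.0104). The lsm8 transcript was higher in lsm8 mutants, with a log2 fold change of 2.87 (SE 0.10, limma adjusted p = 0.000602) in the authors' deposited table. It was also higher in snapc3 mutants, at 2.19 (SE 0.07, limma adjusted p = 0.00213) in the authors' deposited table. The RNA level of a mutant allele does not by itself check a label, because the mutations are not given in the sources used here.

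In snapc3 mutants, 14 of 59 core spliceosome genes are listed as higher and 0 as lower, and 20 of 41 exocrine pancreas genes and 13 of 67 photoreceptor genes as lower and 0 as higher in the authors' deposited table. Summed junction reads, a measure added after the data were seen, cover 25, 13 and 19 members of these lists. Tested as whole sets with camera, the lists do not pass with an estimated correlation (adjusted p = 0.351, 0.351 and 0.389), with which no list passes in any mutant. With a preset correlation they pass (camera adjusted p = 1.41e-11, 9.50e-15 and 0.000148), so the set result depends on this setting. The authors' deposited table lists 464 genes, 140 higher and 324 lower than in wild type. All 14 listed identifiers of the core spliceosome list were higher in the authors' deposited table (Fisher's exact test of direction, adjusted p = 1.77e-07). They include prpf31, a factor of the tri-snRNP, at a log2 fold change of 1.71 (SE 0.07, adjusted p = 0.00252), and the Sm proteins snrpe at 1.29 (SE 0.04, adjusted p = 0.00213) and snrpf at 1.17 (SE 0.05, adjusted p = 0.00346), as limma gave them in the authors' deposited table. Of the LSm and U6 metabolism list, lsm8, lsm7 at 1.54 and ssb at 1.01 were higher in the authors' deposited table and 0 members were lower. The snRNA transcription list split, with brf2 at 2.90 and snapc4 at 1.83 higher, and snapc3 and the Integrator gene ints12 at −7.39 (SE 1.07, limma adjusted p = 0.033) lower in the authors' deposited table. The average log2 expression of ints12 in the authors' deposited table is −2.35, so this fold change rests on few reads.

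The listed members of the digestive and photoreceptor lists were lower in snapc3 mutants. All 20 listed members of the exocrine pancreas list were lower in the authors' deposited table (Fisher's exact test, adjusted p = 0.00184). The pancreatic amylase amy2a had a log2 fold change of −5.10 (SE 0.55, limma adjusted p = 0.0178), the carboxypeptidase cpa1 −4.68 (SE 0.33, limma adjusted p = 0.00835) and the elastase ela2 −4.38 (SE 0.37, limma adjusted p = 0.0109) in the authors' deposited table. All 13 listed photoreceptor genes were lower in the authors' deposited table (Fisher's exact test, adjusted p = 0.0152), among them the rod regulator nr2e3 at −1.86 (SE 0.20, limma adjusted p = 0.0178). All 7 listed intestine genes were lower, among them the fatty acid binding protein fabp2 at −1.75 in the authors' deposited table, but this direction did not differ from that of the other listed genes (Fisher's exact test, adjusted p = 0.119). Other listed rises included the interferon-induced isg15 at 4.47 (SE 0.53, limma adjusted p = 0.0224) and the catenin gene ctnnd1 at 3.61 (SE 0.50, limma adjusted p = 0.0298) in the authors' deposited table. The average log2 expression of isg15 there is −0.64. The interferon and innate list split, with 2 members higher and 1 lower, mhc1zba at −3.55 (SE 0.25, limma adjusted p = 0.00809), in the authors' deposited table. Pancreatic proteases belong to families with similar copies whose reads can be shared, and 114 of the 464 genes in the authors' deposited table have an average log2 expression below 0.

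Skipped exons in snapc3 mutants mostly went to lower inclusion. Of 22314 tested exons 154 were called by limma, 145 lower and 9 higher (exact binomial p = 9.87e-33), and 242 without the control library in position 1. An exon of TMEM120A fell from 97.8% ± 3.87 to 43.0% ± 7.11 (SD, n = 3 per group, limma adjusted p = 0.00061), and one of acsbg1 from 100% ± 0 to 52.1% ± 7.15 (SD, n = 3 per group, limma adjusted p = 6.1e-05). In the SR protein gene srsf3a an exon fell from 99.8% ± 0.211 to 86.0% ± 2.86 (SD, n = 3 per group, limma adjusted p = 0.000619). Of the 127 genes with a called exon, 21 were also in the authors' deposited table, against 2.2 for independent lists (Fisher's exact test, p = 3.33e-15), and all 21 were lower there. They include gda, dpep1, cyp3c4, SPINK4 and the pancreatic regulator rbpjl, named here after their values were seen.

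Retained introns in snapc3 mutants gave 0 calls among 675 tested by limma, with 63 at an unadjusted p below 0.05. The deposited FDR with the same minimum difference gave 17, of which 6 were higher and 11 lower, and a quasi-binomial model gave 0, with 48 at an unadjusted p below 0.05. Mean retention over tested introns was 37.7% ± 0.781 in controls and 37.3% ± 0.371 in snapc3 mutants (SD, n = 3, exact permutation p = 0.6). Of the 675 introns 290 (43.0%, exact interval 39.2% to 46.8%) lay above the controls, with a median difference of −0.173 percentage points (bootstrap interval −0.317 to −0.0663).

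In lsm8 mutants, 28 identifiers of the 59 core spliceosome genes are listed as higher and 0 as lower in the authors' deposited table. They again hold prpf3 under separate identifiers. Listed as lower there are 19 of 41 exocrine pancreas genes, 12 of 45 intestine genes and 9 of 67 photoreceptor genes, and 0 as higher. Summed junction reads cover 27, 12, 22 and 23 members of these lists. As whole sets in camera they do not pass with an estimated correlation (adjusted p = 0.351, 0.351, 0.389 and 0.389). With a preset correlation they pass (camera adjusted p = 5.12e-13, 5.77e-13, 1.05e-11 and 3.95e-08), so the set result depends on this setting. The authors' deposited table lists 851 genes, 427 higher and 424 lower. All 28 listed core spliceosome identifiers were higher in the authors' deposited table (Fisher's exact test, adjusted p = 5.20e-08), including the U5 proteins eftud2 at a log2 fold change of 2.48 (SE 0.06, limma adjusted p = 0.000242) and snrnp200 at 2.32 (SE 0.07, limma adjusted p = 0.000327) and the U2 protein sf3a2 at 2.03 (SE 0.06, limma adjusted p = 0.000466). In the LSm and U6 list 4 genes were higher and 0 lower, with lsm7 at 2.85 and lsm6 at 1.45 beside lsm8 in the authors' deposited table. In the snRNA transcription list 4 genes were higher and 0 lower, led by brf2 at 3.83 (SE 0.10, limma adjusted p = 0.000285) and snapc4 at 3.82 (SE 0.19, limma adjusted p = 0.00153) in the authors' deposited table.

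Of 40 genes of the T lymphocyte list, 4 were listed in lsm8 mutants, all lower in the authors' deposited table. These are the recombination genes rag1 at −2.36 (SE 0.36, limma adjusted p = 0.0261) and rag2 at −1.48 (SE 0.26, limma adjusted p = 0.0361), coro1a at −1.12 (SE 0.08, limma adjusted p = 0.00443) and si:dkey-184p9.9 at −2.36 (SE 0.42, limma adjusted p = 0.0364) in the authors' deposited table. The average log2 expression in the authors' deposited table is −1.47 for rag2 and −6.37 for si:dkey-184p9.9, so these fold changes rest on few reads. Of the myeloid list 3 genes were lower and 0 higher in lsm8 mutants in the authors' deposited table. These are lcp1 at −1.28, mfap4 at −2.59 and cpa5 at −2.93, so the falls were not confined to the T lymphocyte list. However, cpa5 was lower in all mutants, as were exocrine pancreas genes, so its fall need not concern myeloid cells. With fewer than 5 listed members the T lymphocyte list was not tested for direction. Junction reads summed per gene, a measure added after the data were seen, cover 6 other members of the list and lean the other way, with a median log2 change of 0.29, 5 of 6 above 0, and 1 called higher (bcl11ba, named after its value was seen) and 0 lower by limma. In the snapc3 and tnpo3 tables of the authors 0 members of this list appear, and a difference between mutants was not tested. All 19 listed pancreas genes were lower in lsm8 mutants (adjusted p = 5.32e-06), as were all 12 intestine genes (adjusted p = 0.000595) and all 9 photoreceptor genes (adjusted p = 0.00285), by Fisher's exact test on the authors' deposited table. Examples in the authors' deposited table are ela2 at −4.64 (SE 0.36), amy2a at −4.37 (SE 0.37), fabp2 at −2.04 (SE 0.15) and the recoverin gene rcvrna at −1.41 (SE 0.09). Of the 851 genes, 315 have an average log2 expression below 0 in the authors' deposited table.

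**Figure D1:**
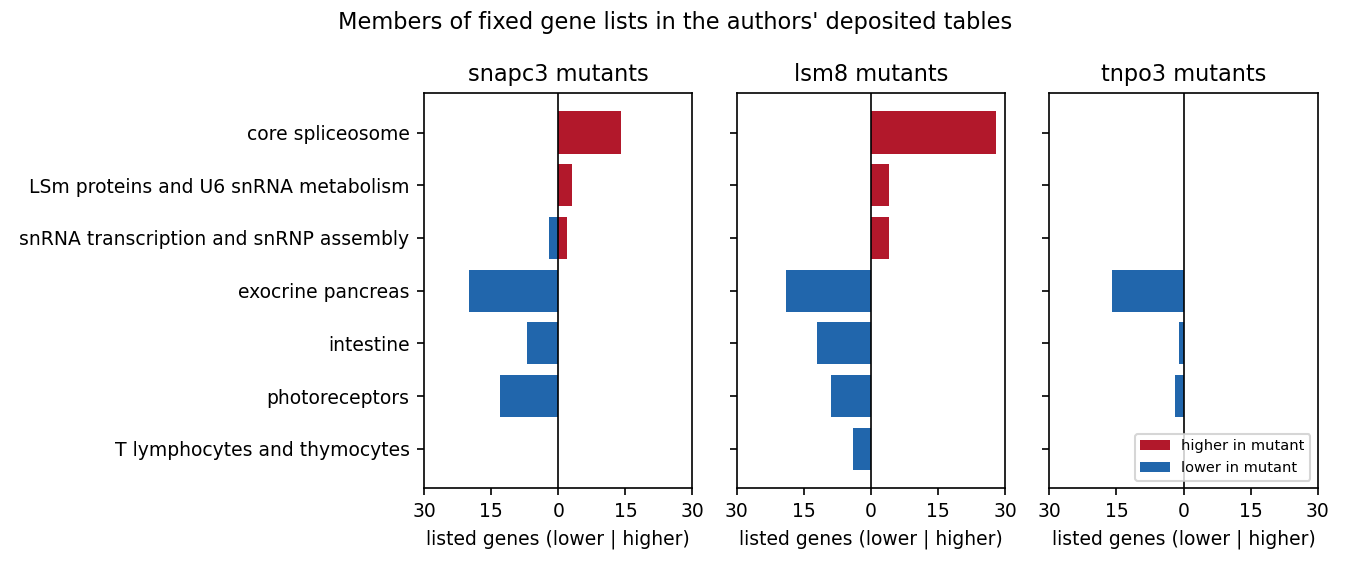
Number of genes of 7 fixed lists in the authors' deposited tables, drawn to the right where higher and to the left where lower in each mutant than in wild type. All 14 and 28 listed core spliceosome identifiers, with prpf3 counted more than once, are higher in snapc3 and lsm8 mutants. All 20, 19 and 16 listed exocrine pancreas genes are lower in snapc3, lsm8 and tnpo3 mutants.

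Intron retention was higher over most introns in lsm8 mutants. Of 677 tested introns, 487 (71.9%, exact interval 68.4% to 75.3%) lay above the controls, with a median difference of 1.25 percentage points. Mean retention was 38.1% ± 0.669 in controls and 40.9% ± 0.328 in lsm8 mutants (SD, n = 3), every mutant library lying above every control library (exact permutation p = 0.1, the smallest that 3 against 3 libraries can give). By limma 11 introns were called, 9 higher and 2 lower (exact binomial p = 0.0654). The largest call was a 66 bp intron of NGRN on chromosome 8 (25889496 to 25889561, build Zv9), which rose from 5.87% ± 5.45 to 51.4% ± 16.6 retention (SD, n = 3 per group, limma adjusted p = 0.0466). An intron of C19H6orf52 rose from 13.3% ± 2.02 to 53.8% ± 13.2 (SD, n = 3 per group, limma adjusted p = 0.0459). One of mlh3, a mismatch repair gene, rose from 54.1% ± 8.42 to 87.3% ± 0.162 (SD, n = 3 per group, limma adjusted p = 0.0459). An intron of C6H1orf159 instead fell from 37.5% ± 12.1 to 5.87% ± 2.58 (SD, n = 3 per group, limma adjusted p = 0.0459). One of uspl1, a SUMO protease gene, rose from 78.9% ± 4.25 to 97.0% ± 0.355 (SD, n = 3 per group, limma adjusted p = 0.038). The 9 introns with higher retention had a median length of 81 bp and those not called 98 bp (permutation p = 0.351). The single calls are fragile, since leaving out any library left 0 to 2 introns and a quasi-binomial model called 0, with 126 at an unadjusted p below 0.05. The deposited FDR with the same minimum difference gave 71 introns, 60 higher and 11 lower.

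**Figure D2:**
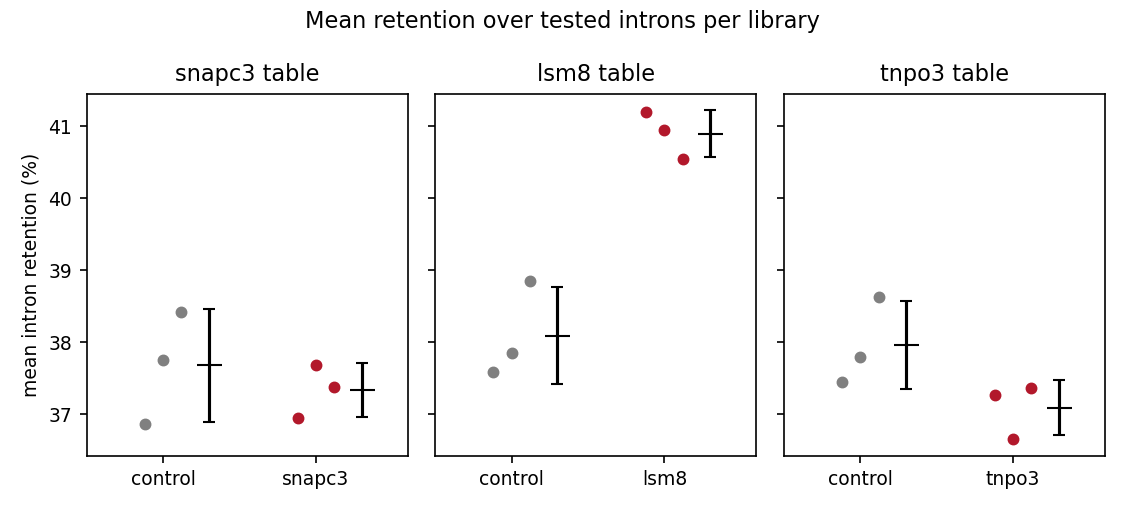
Mean intron retention in percent over all tested introns, 1 point per library, for the controls and the mutant of each retained-intron table, with the mean and SD of 3 libraries beside the points. The vertical axis does not start at 0, and the lsm8 mutant libraries (mean 40.9%) all lie above the controls (mean 38.1%).

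Skipped exons in lsm8 mutants also went mostly to lower inclusion. Of 22499 tested exons 260 were called by limma, 239 lower and 21 higher (exact binomial p = 5.23e-48), with 148 without the lsm8 mutant library in position 1 and 417 without the control library in position 3. An exon of RETSAT fell from 100% ± 0 to 22.5% ± 9.77 (SD, n = 3 per group, limma adjusted p = 7.19e-06), though this exon has a mean of 20.3 reads and a deposited FDR of 1. One of the Fanconi anaemia gene fancc fell from 81.6% ± 10.5 to 13.4% ± 4.68 (SD, n = 3 per group, limma adjusted p = 6.72e-05). In mdm4 an exon on chromosome 11 (23843914 to 23843978, build Zv9) fell from 94.2% ± 5.04 to 52.8% ± 9.99 (SD, n = 3 per group, limma adjusted p = 0.00111). In tox, a gene of thymocyte development, an exon fell from 100% ± 0 to 88.7% ± 9.45 (SD, n = 3 per group, limma adjusted p = 0.0449), a call that was lost whichever library was left out. Of 238 genes with a called exon 10 were in the authors' deposited table, 4 higher and 6 lower there, against 6.33 for independent lists (Fisher's exact test, p = 0.148).

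In tnpo3 mutants, 16 of 41 exocrine pancreas genes are listed as lower and 0 as higher in the authors' deposited table. Summed junction reads cover 14 members of this list. As a whole set in camera it does not pass with an estimated correlation (adjusted p = 0.296). With a preset correlation it passes (camera adjusted p = 1.28e-16), so the set result depends on this setting. Listed as well are 1 intestine and 2 photoreceptor genes, all lower in the authors' deposited table. By summed junction reads 4 of 22 intestine genes and 4 of 24 photoreceptor genes were called lower by limma and 0 higher. Their list medians were −0.95 and −0.48 on the log2 scale. Both lists pass in camera with a preset correlation (adjusted p = 1.61e-06 and 1.37e-07) but not with an estimated one (adjusted p = 0.389 for both). The authors' deposited table lists 115 genes, 38 higher and 77 lower. All 16 listed pancreas genes were lower in the authors' deposited table (Fisher's exact test, adjusted p = 0.00217), with ela2 at a log2 fold change of −3.36 (SE 0.26, limma adjusted p = 0.0266), amy2a at −2.55 (SE 0.17, limma adjusted p = 0.0212) and cpa1 at −2.35 (SE 0.15, limma adjusted p = 0.0212). The list of SR proteins, their kinases and import receptors, which holds tnpo3 itself, had srsf1b higher at 1.28 (SE 0.08, limma adjusted p = 0.0212) and tnpo3 lower in the authors' deposited table. Other rises in the authors' deposited table were the cell cycle inhibitor cdkn1ba at 2.27 (SE 0.08, limma adjusted p = 0.0104), the mitotic kinesin kif11 at 1.27 (SE 0.12, limma adjusted p = 0.0347) and nkx3.2 at 1.86 (SE 0.20, limma adjusted p = 0.0403). The lists of the core spliceosome, LSm proteins and snRNA transcription had 0 listed genes in the authors' deposited table for tnpo3 mutants.

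Skipped exons in tnpo3 mutants again went mostly to lower inclusion. Of 27050 tested exons 591 were called by limma, 560 lower and 31 higher (exact binomial p = 1.18e-126). The exons that fell were long, with a median of 163 bp against 119 bp for exons not called, while 10000 draws of other exons matched on reads and control inclusion gave medians of 113 to 125 bp (permutation p = 0.0001, the smallest these draws can give, adjusted p = 0.00024). The exons that fell in snapc3 and lsm8 mutants were instead short, with medians of 92 and 96 bp against 105 and 108 bp for exons not called (draws matched in the same way, permutation adjusted p = 0.0305 and 0.0272). Among exons present for all mutants, with draws not matched, the lsm8 median was 94.5 bp against 105 bp and did not pass (permutation adjusted p = 0.0516). The snapc3 median there was 84 bp against 105 bp (permutation adjusted p = 0.015). The medians of 92 and 96 bp lay below that of tnpo3 mutants (permutation p = 1e-05, the smallest the resamples can give, adjusted p = 6e-05), though exons are not independent replicates. A 1636 bp exon of LRIF1 on chromosome 8 (23356403 to 23358038, build Zv9) fell from 100% ± 0 to 25.2% ± 12.1 (SD, n = 3 per group, limma adjusted p = 0.000939), though its deposited FDR is 1. A 1047 bp exon of SPTBN5 fell from 100% ± 0 to 36.4% ± 11.6 (SD, n = 3 per group, limma adjusted p = 4.78e-06). Genes of snRNA transcription and assembly were called more often than others, 7 of 20 tested (SNAPC2, brf1a, gemin5, gemin8, ints1, ints7 and ints8) against 0.892 at the rate of all genes (Fisher's exact test, adjusted p = 0.000629), with 2.55 tested exons per gene and 2.36 in other genes. Of these calls, those in brf1a, gemin8 and gemin5 passed in 4, 3 and 1 of 6 fits without 1 library, and brf1a has a deposited FDR of 1. A 526 bp exon of SNAPC2 fell from 98.1% ± 3.21 to 40.3% ± 19.3 (SD, n = 3 per group, limma adjusted p = 0.00011). In the SR protein list 5 of 31 genes were called (Fisher's exact test, adjusted p = 0.180), and a 398 bp exon of srsf3a went from 18.1% ± 2.42 to 3.16% ± 0.735 (SD, n = 3 per group, limma adjusted p = 0.00227) and one of srsf6b from 36.7% ± 7.21 to 13% ± 2.90 (SD, n = 3 per group, limma adjusted p = 0.0263), the latter kept in only 2 of 6 fits without 1 library (adjusted p up to 0.0844). Of 511 genes with a called exon 5 were in the authors' deposited table, 1 higher and 4 lower there, against 2.1 for independent lists (Fisher's exact test, p = 0.0570). Exon lengths and gene lists among called exons were examined only after the calls were seen.

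**Figure D3:**
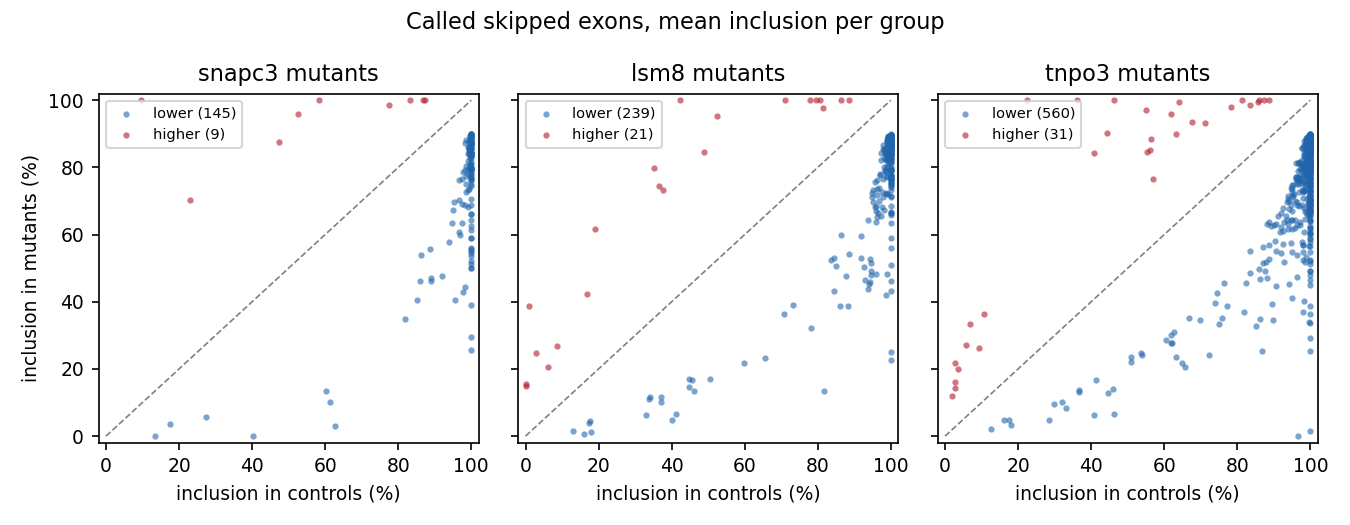
Mean inclusion in percent of each called skipped exon in controls (horizontal axis) and in mutants (vertical axis), with exons of lower inclusion in blue and of higher inclusion in red. Most called exons lie below the diagonal, 145 of 154 in snapc3, 239 of 260 in lsm8 and 560 of 591 in tnpo3 mutants, and many start near full inclusion.

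Retained introns in tnpo3 mutants gave 0 calls among 675 tested by limma, with 59 at an unadjusted p below 0.05. The deposited FDR with the same minimum difference gave 31, of which 7 were higher and 24 lower, and these genes include srsf1b and tnpo3 itself. A quasi-binomial model gave 0, with 46 at an unadjusted p below 0.05. Mean retention was 38.0% ± 0.608 in controls and 37.1% ± 0.382 in tnpo3 mutants (SD, n = 3, exact permutation p = 0.1, the smallest possible), every mutant library lying below every control library. Of the 675 introns 250 (37.0%, exact interval 33.4% to 40.8%) lay above the controls, with a median difference of −0.346 percentage points (bootstrap interval −0.496 to −0.254).

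The mutants shared many listed genes. Between snapc3 and lsm8 mutants 183 genes were in both of the authors' deposited tables, 58 higher in both, 124 lower in both and only the carbonic anhydrase gene ca4b of opposite sign. Independent lists would share 1.77 higher and 4.07 lower genes. Such expectations give each of the 33737 genes tested the same chance of being listed, whatever its reads, so they can be too low. With tnpo3 mutants, snapc3 mutants shared 46 listed genes (2 higher and 42 lower in both) and lsm8 mutants 44 (6 higher and 38 lower in both) in the authors' deposited tables, against 0.739 and 0.968 lower genes for independent lists. There are 35 genes in all of the authors' deposited tables, 34 of them lower in every mutant, and 14 of these belong to the exocrine pancreas, such as ela2, amy2a, cpa1, cpb1, ctrb1 and try. The genes chia.3, an intestinal chitinase, and cpa5 were also lower in all mutants in the authors' deposited tables. Part of any excess may come from the shared controls, which cannot be split into groups of at least 2 libraries. In simulations of unchanged groups with shared controls 0 genes were called in both, and genes that passed an unadjusted threshold in both had the same sign in 99.8%, 99.9% and 99.95% of cases for the pairs in the order above. These simulations hold no changed gene, so shared calls could hardly arise. They cannot show how much of the sharing comes from the controls.

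**Figure D4:**
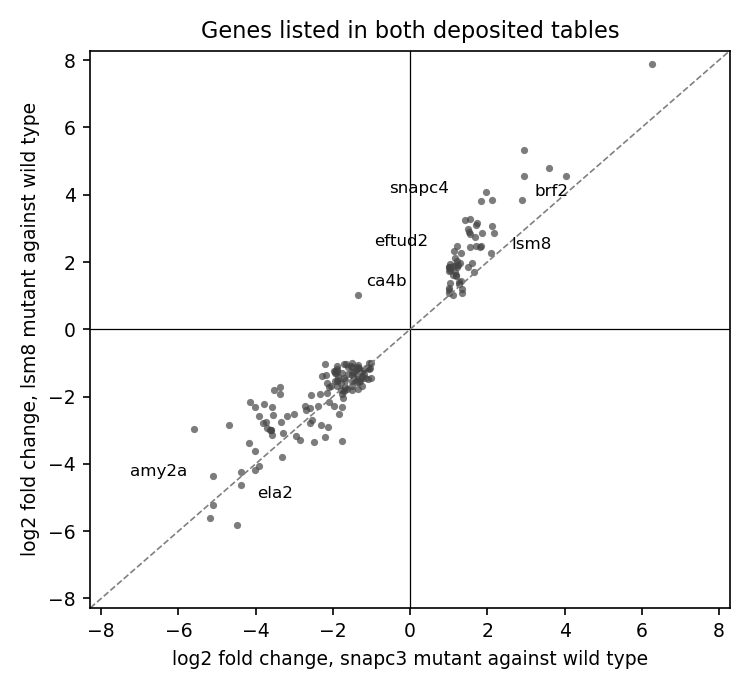
Log2 fold change against wild type in lsm8 mutants (vertical axis) and in snapc3 mutants (horizontal axis) for the 183 genes in both of the authors' deposited tables, 1 point per gene, with the line of equal change dashed. Of these genes 182 have the same sign in both, and ca4b is the exception.

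The mutants also shared some skipped exons. Among skipped exons tested in both tables, 9 were called in the same direction in snapc3 and lsm8 mutants, 16 in snapc3 and tnpo3 mutants and 24 in lsm8 and tnpo3 mutants, and 0 in opposite directions. Independent lists would share 1.19, 2.2 and 4.0 exons of lower inclusion, an expectation that ignores the shared controls and gives every exon the same chance of a call. In simulations of unchanged groups with shared controls 0 exons were called in both. At an unadjusted limma p below 0.05 in both, 699, 659 and 753 exons passed, against 138, 136 and 135 simulated. These simulations hold no changed exon, so they cannot show how much of the sharing comes from the controls. Across exons, the covariance of the log2 changes exceeded that of simulated unchanged groups with shared controls by 0.305, 0.296 and 0.283, but the Pearson correlations of 0.426, 0.396 and 0.384 lay below the simulated 0.4997, 0.498 and 0.502, so these measures do not point one way. An exon of gemin8 on chromosome 1 (27991654 to 27991735, build Zv9) fell from 85.9% ± 9.05 to 46.2% ± 2.71 in snapc3 mutants (SD, n = 3 per group, limma adjusted p = 0.0159) and to 49.8% ± 9.44 in tnpo3 mutants (SD, n = 3, limma adjusted p = 0.0142), calls kept in 5 and 3 of 6 fits without 1 library (adjusted p up to 0.0735 and 0.0874). An exon of srrm1 fell from 44.7% ± 7.80 to 17.0% ± 2.83 in lsm8 mutants (SD, n = 3 per group, limma adjusted p = 0.0282) and to 12.9% ± 7.03 in tnpo3 mutants (SD, n = 3, limma adjusted p = 0.00741), calls kept in 2 and 5 of 6 fits without 1 library (adjusted p up to 0.103 and 0.0547). Retained introns allow no such count by limma, since 0 were called in snapc3 and tnpo3 mutants, and the deposited FDR gave 7, 5 and 5 shared introns.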

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

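Pairs of mutants were compared directly by limma because an effect in one mutant and none in another shows no difference by itself, and this contrast was chosen before the data were examined. All tests of explanations and all splits of libraries in this part were chosen only after the results were seen. Of 651 retained introns tested in both tables, 35 differed between snapc3 and lsm8 mutants, 31 of them with more retention in lsm8 mutants. Between lsm8 and tnpo3 mutants 51 of 657 differed, 45 with more retention in lsm8 mutants. Between snapc3 and tnpo3 mutants 1 of 653 differed, an intron of srsf1b with 73.4% ± 4.25 retention in snapc3 mutants, 96.6% ± 0.639 in tnpo3 mutants and 84.1% ± 3.1 in controls (SD, n = 3 per group, limma adjusted p = 0.0115). Of the skipped exons, 153 of 14390 differed between snapc3 and lsm8 mutants (101 with more inclusion in snapc3), 291 of 14884 between snapc3 and tnpo3 mutants (210 with more in snapc3) and 355 of 14756 between lsm8 and tnpo3 mutants (206 with more in lsm8).

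The first pattern weighed is the difference between mutants, for which the strain backgrounds offer a technical explanation, since each control library has its own background. If strain variants set inclusion at these events, the control libraries would differ from each other there more than at other events. At 611 differing exons the median SD between control libraries was 2.76 points, above the 1.66 to 2.1 points of 10000 draws of exons matched on reads and inclusion, so strain variants may account for part of these differences. An example is an exon of sfswap with 0.735% ± 0.684 inclusion in snapc3 mutants, 97.5% ± 1.17 in lsm8 mutants and 35.9% ± 30.8 in controls (SD, n = 3 per group, limma adjusted p = 0.00444). At the 50 matched introns the SD was 3.30 points, within the draws of 2.60 to 4.02, so mutation and background cannot be told apart there, and the mutation itself stays open as the other explanation throughout.

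The second pattern is that called skipped exons mostly went to lower inclusion. Events found only in mutant reads could add to this, so exons with at least 1 skipping read in the controls were counted alone. Of these, 88.3% of 77 (exact interval 79.0% to 94.5%), 86.6% of 157 (80.3% to 91.5%) and 89.9% of 308 (86.0% to 93.1%) fell in snapc3, lsm8 and tnpo3 mutants. The direction is thus not confined to exons skipped only in mutant reads. Such exons can still lie near full inclusion, where a ceiling keeps the split uneven, so this count cannot weigh how much those events add. A ceiling, where exons near full inclusion can only fall, may account for part of the direction. Among exons with 20 to 80% control inclusion, 65.4% of 26 fell in lsm8 mutants (44.3% to 82.8%) and 66.7% of 48 in tnpo3 mutants (51.6% to 79.6%). Both shares are below those of all calls. They are nearly equal, and the tnpo3 interval lies above 50% with more exons, so the lsm8 and tnpo3 mutants are not told apart here. In snapc3 mutants 50% of 10 (18.7% to 81.3%) is too few to decide. A second bin, a mean inclusion of 20 to 80% over both groups, was also tried but decides nothing, because a fall itself moves an exon into it, and loss of exon recognition in the mutants stays open.

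The third pattern is the rise of intron retention in lsm8 mutants. Genomic DNA in the libraries would add the same number of reads to every intron and hardly move those with the most reads, but in the top 25% of introns by reads the median rise was 0.481 points (bootstrap interval 0.299 to 0.771) where dilution of the rise of 2.49 points in the bottom 25% predicts 0.106. Controls with unusually low retention would raise all mutants, but the highest share of introns above the controls in the other mutants was 43.0% (upper limit 46.8%). The lowest lsm8 mutant library lay 1.70 points above the highest control library, where the controls span 1.27 points, but only 1 control library has the background of the lsm8 mutants, so strain background and mutation cannot be told apart. An effect of the lsm8 mutation on splicing therefore stays open, as untested. So do the fewer junction reads of the lsm8 mutant libraries in these events, whose total library sizes are not known.

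Other splits of the 6 libraries of a comparison can test chance only weakly, because 3 against 3 libraries make 10 splits and the share of splits can never be below 0.1. For retained introns, the real split called 0, 11 and 0 in snapc3, lsm8 and tnpo3 mutants by limma, with 63, 155 and 59 at an unadjusted p below 0.05, the highest other split called 2, 1 and 1, and 10, 1 and 10 splits called as many as the real one. The deposited FDR gave 17, 71 and 31 introns and the quasi-binomial model 0 in each. For skipped exons the real split called 154, 260 and 591 and the highest other 3, 2 and 1, and for genes by summed junction reads 279, 343 and 130 against 1, 1 and 4, with 1 split as large in each. For differences between mutants (snapc3 and lsm8, snapc3 and tnpo3, lsm8 and tnpo3), retained introns gave 35, 1 and 51 against 0, 1 and 1, with 1, 2 and 1 splits as large, and skipped exons 153, 291 and 355 against 0 in each, with 1 split as large in each.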

How the results depend on the processing

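The fit of summed junction reads and the 4 restrictions of the direction test (control inclusion, mean inclusion, control skipping reads, exons in the tables of all mutants) were chosen only after the data were seen, and the other alternatives were planned. No paired analysis was possible because cells of the splicing tables hold 3 counts with no replicate numbers, the deposited expression tables have no values per library, and each control library has another strain background. For the same reasons a replicate block and, for expression, leaving out replicates were not run. A stricter threshold cannot turn a sign. Among alternatives that could, 0 of the 43 named splicing events reversed, while by summed junction reads 1 of 261 listed genes in lsm8 mutants, SNRPG, had the opposite sign (log2 change −1.61, SE 3.32). Where counts moved by more than 1.5 times, the cause was not tested except that stricter limits call fewer by construction. At an adjusted p below 0.01 the authors' deposited tables hold 85, 233 and 0 genes for snapc3, lsm8 and tnpo3 (lowest adjusted p for tnpo3 0.0104), 3 of the 4 list tests that still have enough genes pass in place of 9 of 11, and 45, 0 and 0 genes are shared between snapc3 and lsm8, snapc3 and tnpo3, and lsm8 and tnpo3. With symbols only, 554 genes stay for lsm8. Summed junction reads gave 279 genes for snapc3 and 343 for lsm8. Called retained introns in snapc3, lsm8 and tnpo3 mutants became 17, 71 and 31 with the deposited FDR. For lsm8 they became 20 with a pseudocount of 2, 21 with no minimum difference, 7 with 20 points, 18 in a fit over all groups, 0 with no read minimum (limma, 150 at an unadjusted p below 0.05) and 0 with the quasi-binomial model (126 unadjusted). Called skipped exons became 317 and 479 in snapc3 and lsm8 mutants with the deposited FDR, and in snapc3, lsm8 and tnpo3 mutants 584, 968 and 1693 with no minimum difference, 79, 120 and 290 with 20 points, 55, 90 and 249 in a fit over all groups (fewer exons tested), and 0, 0 and 0 with the quasi-binomial model (1640, 2036 and 3102 unadjusted). Leaving out 1 library at a time gave 0 to 2 introns in each mutant, and 126 to 242, 148 to 417 and 437 to 669 exons, with 242 without the control library in position 1 (snapc3) and, for lsm8, 417 without the control library in position 3 and 148 without the mutant library in position 1. Shared events with the deposited FDR were 7, 5 and 5 introns and 46, 43 and 80 exons. The median length of introns with more retention in lsm8 mutants was 81 bp with the deposited FDR (permutation p = 0.0359). In lsm8 mutants 15.7% of the 70 tested introns called with the deposited FDR were lower (exact binomial p = 4.47e-09) and 16.7% of 12 called by limma with at least 20 reads (p = 0.0386). With control inclusion of 20 to 80%, 50% of called exons were lower in snapc3 mutants (exact binomial p = 1) and 65.4% in lsm8 mutants (p = 0.169). Of 43 named events 25 passed in every fit without 1 library, 18 were lost in at least 1 and 43 were lost with the quasi-binomial model. Of 145 named genes 52 passed at 0.01. At this depth 27.3%, 32.3% and 38.8% of exon changes of 3 log2 units, simulated away from full inclusion, were called in the snapc3, lsm8 and tnpo3 settings.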

Other observations

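The tests of summed junction reads and the look at small RNA families in this part were chosen only after the data were seen. Junction reads of the skipped-exon tables, summed per gene and tested by limma, cover genes that the authors' deposited tables leave out. By this measure 279 of 9985 genes passed in snapc3 mutants, 343 of 9771 in lsm8 and 130 of 11139 in tnpo3 mutants, at an adjusted p below 0.05 and an absolute log2 change of at least 1. Of genes also in the authors' deposited tables, 174 of 174, 260 of 261 and 46 of 46 had the same sign. The median change of all genes was −0.11, 0.11 and 0.02 on the log2 scale, which the following values include.

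Of 29 measured skeletal muscle genes, 12 were higher and 0 lower in snapc3 mutants at an adjusted p below 0.05 by limma, with a median log2 change of 0.51 over the list, where the authors' deposited table lists 1 gene of this list. Of the 29 genes 0 reached an absolute log2 change of 1 at an adjusted p below 0.05 by limma, and as a set the list has an adjusted p = 0.351 with an estimated correlation in camera. Examples, chosen after their values were seen, are tpma at 0.79 (SE 0.08, limma adjusted p = 0.000835), ckma at 0.59 (SE 0.06, limma adjusted p = 0.000837) and mylpfa at 0.65 (SE 0.07, limma adjusted p = 0.0011). In lsm8 mutants 19 of 39 were higher and 1 lower, with a median of 0.36, of which 2 and 1 also reached a log2 change of 1 (camera, adjusted p = 0.351 with an estimated correlation). Of 29 measured cell cycle genes, 0 were higher and 7 lower in snapc3 mutants by limma, with a median of −0.48, of which 3 also reached a log2 change of 1 (camera, adjusted p = 0.296 with an estimated correlation), among them mki67 at −1.11 (SE 0.17, limma adjusted p = 0.00623). In tnpo3 mutants 9 of 44 cell cycle genes were higher and 1 lower, with a median of 0.07, of which 2 and 0 reached a log2 change of 1 (camera, adjusted p = 0.448 with an estimated correlation). One of the 9 is cenpe at 0.99 (SE 0.11, limma adjusted p = 0.00372). The kinesin kif11 went to −0.88 in snapc3 and 1.26 in tnpo3 mutants, and this difference between mutants was not tested. Tested as sets with camera, 22 of 77 combinations of list and mutant passed with a preset correlation and no calls hold with an estimated one.

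Genes of small RNAs are in the authors' deposited tables as well. In snapc3 mutants 4 identifiers of 5S_rRNA are listed, 1 higher and 3 lower, U1 is listed at a log2 fold change of 1.99 (limma adjusted p = 0.0469, average log2 expression −5.30), and RNase_MRP has 1 identifier at a log2 fold change of 10.28 (SE 1.64, limma adjusted p = 0.0407) and another at −4.62 (SE 0.24, limma adjusted p = 0.00417) in the authors' deposited table. In lsm8 mutants 36 identifiers of 5S_rRNA are listed, 35 higher and 1 lower, and U6 is listed at a log2 fold change of 5.76 (SE 0.49, limma adjusted p = 0.00576) in the authors' deposited table. In tnpo3 mutants U3 is listed at 7.82 (SE 0.38, limma adjusted p = 0.0115) in the authors' deposited table. Such genes have near-identical copies and short transcripts, so these values are uncertain, and the median average log2 expression of the 5S_rRNA identifiers in the authors' deposited table for lsm8 mutants is −6.21.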
